A study of Mus musculus with 6 samples.

How the data were processed

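Total RNA from the radii and ulnae of newborn mice of strain 129sv was hybridised to 6 single-colour Affymetrix whole-transcript arrays, 3 from wild-type mice and 3 from littermates carrying the del175k mutation of Tnni2, per the labels. RNA was purified on RNeasy columns, and amplified, fragmented and end-labelled with biotin, per the labels' protocols. The labels speak of pairs of mutant and wild-type littermates but do not say whether each array held the bone of a single mouse, so p-values measure the spread between these samples, which may be partly technical.

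The deposited values were intensities on a linear scale, with 1 summarised brightness for each of 8997 probe sets per array. Background correction, summarisation and scaling between arrays were not given in the sources used here, so which scaling was applied stays unknown. Array medians lay between 39.6 and 48.4 intensity units. Every probe set reached an intensity of 20 on at least 3 of the 6 arrays, which shows a filter by level that the labels do not describe. Such a filter leaves out genes that were dim in both groups or bright on fewer than 3 arrays. Of the 8997 probe sets, 1996 had a value under 20 on at least 1 array, 52 were under 20 on all 3 wild-type arrays and 16 were under 20 on all 3 mutant arrays. Folds of genes this dim depend on background handling that is not stated. The number of arrays limits the precision of every value.

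Gene names came from the platform's annotation of 2016. Exactly 1 gene symbol was listed for 6398 probe sets, several for 576 and none for 2023, and only probe sets with 1 symbol were named. Symbols were checked through Entrez identifiers against the RefSeq gene table of assembly GRCm38.p6, and 0 needed updating. The 5780 named genes included 327 with more than 1 probe set, for which the probe set with the highest mean over the 6 arrays stood for the gene. No coordinates were used, since no genome build was stated for the values.

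Intensities were converted to log2 with no further normalization and no filter. A model with 2 group means was fitted to each probe set with lmFit and eBayes of limma 3.58.1 in R 4.3.3, tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the 8997 probe sets with a threshold of 0.05. Levels are given as the mean ± SD of the intensities of 3 arrays, and log2 differences as mutant minus wild-type with the moderated SE of that fit. Adjusted p-values in the text are from limma. Gene lists were tested on the same fit with camera of limma at a preset correlation between genes of 0.01, which compares the genes of a list with all other genes. They were also tested with camera at an estimated correlation and with fry, which tests whether a list's genes move one way without comparing them with other genes. Of the 36 lists, 30 had at least 3 measured genes and were tested, with p-values adjusted over these 30. The lymphoid, interferon response and sex-linked lists had 0 measured genes, and those for megakaryocytes, brown adipocytes and nerve had 1 each. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 was used for tables and plots.

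The test, the gene lists, the rule for naming genes and the alternatives were fixed before the data were examined. The rule named Tnni2, Hif3a and Vegfa, then up to 12 genes per direction with the largest change among those that passed with groups that did not overlap. Where fewer passed, it took the genes of smallest p in that direction up to 12, skipping predicted genes, olfactory receptors and small non-coding RNAs. In each list it named members that passed, or the 2 of smallest p where none did. The alternatives were quantile normalization, median centring, leaving out the dimmest 25% or the dimmer part of the probe sets, an intensity trend with robust variances, array weights, the replicate number as a block, other thresholds, the ordinary statistic of the same fit, 1 probe set per gene, the mean over all probe sets of a gene, and leaving out each array in turn.

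The procedure was tested on 20 simulated data sets of 8997 probe sets with the means and spreads of this comparison, each with 200 changed probe sets. It recovered 37.4% of 2-fold and 87.2% of 4-fold changes, 4.5% of its calls were false, and a list shifted by -0.4 on the log2 scale was found in 90% of the data sets. The noise was drawn independently for each probe set, and no array was made dimmer. The rate for the list thus does not hold where genes vary together, as the cell division genes did here (estimated correlation 0.607).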

Results

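Gene expression was measured in the forearm long bones of newborn mice, comparing 3 wild-type samples with 3 samples from littermates carrying the Tnni2 del175k mutation. Tnni2 encodes the fast skeletal muscle isoform of troponin I, a regulator of muscle contraction, and mutations in its human counterpart cause distal arthrogryposis. The comparison asks which genes differ in the developing bone of these mutants. The median intensity was 39.6 on the array of wild-type replicate 1, 48.4 and 48.0 on the other wild-type arrays, and 47.6, 45.5 and 47.8 on the mutant arrays. Wild-type replicate 1 stood apart from the rest, with a median probe set at -0.30 on the log2 scale from the mean of the other arrays. Its 1205 probe sets under an intensity of 20 compared with 405 to 558 on the others.

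Tnni2 itself had an intensity of 174.6 ± 78.6 (SD, n = 3) in the wild-type samples and 153 ± 39.2 (SD, n = 3) in the mutant samples. Its log2 difference was -0.12 ± 0.33 (SE, limma adjusted p = 0.943). The mutation removes a codon, which need not change the level of the transcript, so this level does not check the genotype labels. Hif3a, a member of the hypoxia-inducible factor family that can restrain the other members, was at 10.8 ± 2.36 in the wild-type and 35.8 ± 10.6 in the mutants (SD, n = 3 each). Its log2 difference was 1.71 ± 0.28, or 3.27-fold, with all 3 mutant arrays above all 3 wild-type arrays, but it did not pass over all probe sets (limma adjusted p = 0.313). Vegfa, which encodes the main angiogenic growth factor of bone, was at 43.3 ± 8.23 and 49.5 ± 11.0, a log2 difference of 0.19 ± 0.24 (adjusted p = 0.851).

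All wild-type values of Hif3a lay under 20, so the filter by level kept it only because all 3 mutant arrays reached 20. That its groups did not overlap was thus fixed in advance. Its log2 difference was 1.98 both with array weights (adjusted p = 0.0414) and without mutant replicate 3 (adjusted p = 0.0317). With each array left out in turn the adjusted p of Hif3a ranged from that 0.0317 up to 0.983. The direction of Vegfa turned with array weights (-0.065), and that of Tnni2 turned without wild-type replicate 3 (0.21) and without mutant replicate 2 (0.001), while it was at -0.46 without wild-type replicate 1 and -0.56 with array weights.

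The genes with the smallest p-values had higher levels in mutant bone. Depp1, a regulator of autophagy induced by FoxO factors, was at 10.2 ± 2.35 in the wild-type and 43.7 ± 13.0 in the mutants (SD, n = 3), a log2 difference of 2.08 ± 0.26. Ddit4, an inhibitor of the growth kinase complex mTORC1, was at 26.6 ± 5.65 and 122.8 ± 49.7, a log2 difference of 2.14 ± 0.33. Angptl7, a secreted angiopoietin-like protein, had the largest difference among the named genes, 3.99 ± 0.79, from 13.9 ± 5.35 to 335 ± 296.6. Its mutant arrays were far apart, at 638, 323 and 44.7. All wild-type values of Depp1 and Angptl7 lay under 20, so the size of these differences depends on background handling that is not stated.

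None of these genes passed at an adjusted p of 0.05. The smallest adjusted p-values were those of Depp1 (0.155), Msmp (0.164), Ddit4 (0.231) and Hif3a (0.313). The log2 difference of Msmp, which encodes a microseminoprotein, was 1.63 ± 0.23. Bmf, which encodes a BH3-only protein that promotes apoptosis, followed at 1.09 ± 0.19, from 24.6 to 52.0. Ccng2, for cyclin G2, was at 1.08 and Klhl6 at 1.03. Pik3ip1, an inhibitor of phosphoinositide 3-kinase, was at 1.47, and Pik3r1, a regulatory subunit of that kinase, at 1.23. Adh1, an alcohol dehydrogenase, was at 2.27, and Trp53inp1, a p53-inducible stress protein, at 2.19. In each of these 12 genes all mutant values lay above all wild-type values. In Depp1, Msmp, Hif3a, Ccng2, Angptl7, Pik3ip1 and Klhl6 all wild-type values lay under 20. A probe set this dim in the wild-type was kept only if all 3 mutant arrays reached 20. The filter by level thus fixed this order in advance for these genes, and their folds depend on background handling that is not stated.

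The 12 genes of smallest p with lower levels in mutant bone did not pass either. Crip1, which encodes a LIM-domain protein, was at 143 ± 20.4 in the wild-type and 72.5 ± 11.7 in the mutants (SD, n = 3), a log2 difference of -0.98 ± 0.21 (limma adjusted p = 0.42). Mybpc2, the fast-fibre form of myosin-binding protein C, was at 48.0 ± 17.5 and 19.6 ± 4.08, a log2 difference of -1.25 ± 0.28 (adjusted p = 0.441). Spon2, which encodes a secreted matrix protein, differed by -1.42 ± 0.34 (adjusted p = 0.478). The tubulin gene Tuba1a was at 614.8 and 379.5 (-0.70 ± 0.22), the tropomyosin gene Tpm4 at -0.69 and the tubulin-binding Tppp3 at -0.93. The histone variant gene H2ax was at -0.87, the membrane protein gene Emp3 at -0.92, the small GTPase gene Rrad at -0.82 and the phosphatase gene Dusp14 at -0.92. Naaa, for a lipid amidase, was at -0.72 and Gltp, for a glycolipid transfer protein, at -0.73. In each of these 12 genes all mutant values lay below all wild-type values. For Naaa, under 20 on all 3 mutant arrays, the filter by level fixed this order in advance.

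**Figure D1:**
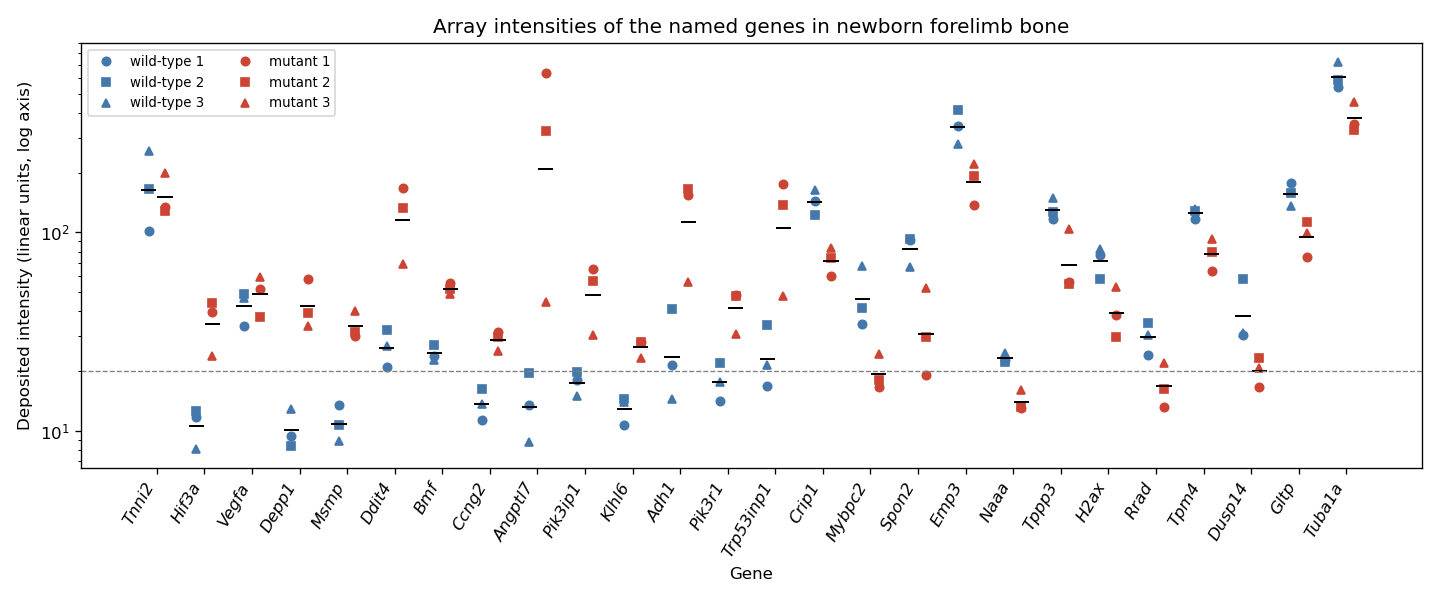
Intensity (log scale) of the named genes on each array, with wild-type and mutant arrays as separate points, bars at the geometric mean of each group and a dashed line at an intensity of 20. Hif3a, Depp1 and Ddit4 show all 3 mutant points above all 3 wild-type points, while Tnni2 and Vegfa overlap. For Hif3a and Depp1, under 20 on all wild-type arrays, the filter by level left no other order possible.

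Over the 8997 probe sets, limma called 0 higher and 0 lower in the mutants, and the ordinary statistic of the same fit also called 0. At an unadjusted p under 0.05 there were 669 probe sets, 516 higher and 153 lower, where 449.85 would be given by chance. All mutant values lay above all wild-type values in 826 probe sets and below them in 350, together 13.07% of probe sets, against 10% by chance. The filter by level fixed this order for the 52 probe sets under 20 on all wild-type arrays and the 16 under 20 on all mutant arrays. A difference of at least 2-fold was seen in 67 of the 826 and in 7 of the 350. The median log2 difference over all probe sets was 0.045, so more of them had higher than lower means in the mutants. Without wild-type replicate 1 this median was -0.033. Counts of higher and lower list members, given below, do not allow for this background, while shifts relative to the other genes do.

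The share of higher probe sets among those at an unadjusted p under 0.05 was 77.1%. It was 62.3% after quantile normalization (532 higher, 322 lower), 66.0% after median centring (570 and 294), 43.6% with array weights (616 and 796) and 48.4% without wild-type replicate 1 (288 and 307). Without mutant replicate 3, limma called 15 probe sets of 14 genes higher, with array weights it called 4, and 3 were called in both; the unadjusted count was 322 without mutant replicate 1 and 393 without mutant replicate 2. The genes called without mutant replicate 3 included Angptl7 (log2 difference 5.10, adjusted p = 0.0034), Ddit4 (2.50, adjusted p = 0.019), Depp1, Hif3a, Pik3ip1, Adh1 and Trp53inp1. The others, named after their values were seen, were Fkbp5 (3.19, adjusted p = 0.019), Tsc22d3 (2.67), Sesn1, Glul, Serpina3n, Mt1 and Mt2. With all arrays, Fkbp5 was at 2.31 (adjusted p = 0.587) and Mt2 at 1.30 (adjusted p = 0.667). In Fkbp5, Sesn1 and Mt2 the groups then overlapped, since the left-out mutant replicate 3 lay below a wild-type array. In Tsc22d3, Mt1 and a probe set of Glul it was the lowest mutant array but lay above all wild-type arrays.

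All 16 measured genes of cell division had lower means in mutant bone, with a mean log2 difference of -0.40. The list fell relative to the other genes by 0.49, which passed with camera's preset correlation (adjusted p = 6.2e-07) but not with an estimated correlation (adjusted p = 0.95). The plain mean of -0.40 did not pass with fry (adjusted p = 0.747). Rrm2, which encodes a subunit of ribonucleotide reductase, was at 34.5 ± 13.4 in the wild-type and 18.6 ± 5.46 in the mutants (SD, n = 3; -0.87 ± 0.31), and Mcm2, part of the replicative helicase, was at 69.4 ± 22.0 and 42.0 ± 12.9 (-0.72 ± 0.30). Neither gene passed by itself, and 0 members passed when adjusted over the list alone.

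All 6 measured epidermal genes had lower means in the mutants too, with a mean log2 difference of -1.82. This list passed with camera's preset correlation (adjusted p = 0.0011), but not with an estimated correlation (adjusted p = 0.95) or with fry (adjusted p = 0.747). Lor, which encodes loricrin of the cornified envelope, was at 72.0 ± 56.3 and 12.5 ± 10.9 (-2.20 ± 0.90), and Krtdap, expressed in differentiating keratinocytes, was at 54.6 ± 48.9 and 10.3 ± 9.28 (-1.94 ± 0.98). Relative to all genes the list stood at 2.92, 2.10 and -2.14 on the wild-type arrays and at -1.60, 0.79 and -2.07 on the mutant arrays (log2). These markers of skin were thus high on wild-type replicates 1 and 2 and on mutant replicate 2. The cell division list stood at 0.37, -0.07 and 0.44 on the wild-type arrays and at -0.39, -0.43 and 0.08 on the mutant arrays.

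Of 10 genes of the unfolded protein response and amino acid stress, 7 had lower means in the mutants. The list fell by 0.30 relative to the other genes, which passed with camera's preset correlation (adjusted p = 0.031) but not with an estimated correlation (adjusted p = 0.95). Its plain mean of -0.21 did not pass with fry (adjusted p = 0.747). The members of smallest p were Phgdh (41.1 ± 2.68 and 31.0 ± 5.94; -0.42 ± 0.21) and Psat1 (43.3 ± 1.21 and 35.7 ± 4.24; -0.29 ± 0.19), enzymes of serine synthesis whose mutant values all lay below the wild-type values. In the epidermal and stress lists 0 members passed when adjusted over the list alone. The epidermal call was lost with array weights (-0.03), without the dimmest 25% of probe sets (-1.95, adjusted p = 0.0905), without wild-type replicate 1 (-0.94, adjusted p = 0.403) and without mutant replicate 3 (-1.37, adjusted p = 0.0557), and its shift was -3.47 without wild-type replicate 3. The stress call was lost at shifts of similar size, without the dimmer part of the probe sets (-0.35, adjusted p = 0.0877), without wild-type replicate 2 (-0.29, adjusted p = 0.0993) and without mutant replicate 3 (-0.32, adjusted p = 0.0557).

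**Figure D2:**
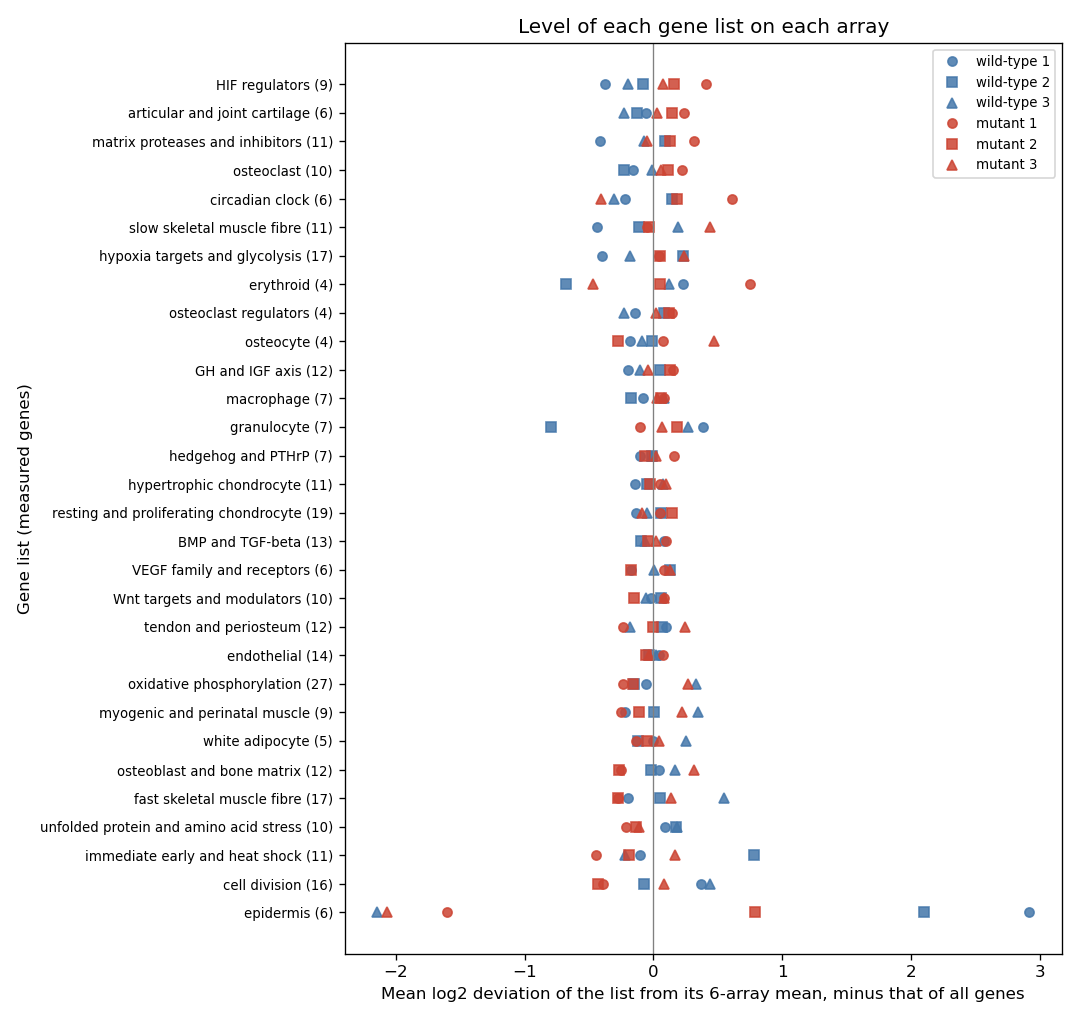
Mean log2 deviation of each gene list from its mean over the 6 arrays, minus that of all genes, with 1 point per array and the number of measured genes in brackets. The epidermal list spreads from -2.14 to 2.92, and wild-type replicate 3 lies beside mutant replicates 1 and 3.

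Skeletal muscle genes lay on both sides of the wild-type level. Some were bright, with Acta1 at 2801 ± 829.7 and Ckm at 678 ± 223.6 in the wild-type samples. Tnni2 rose over wild-type replicates 1 to 3 (101.5, 164.7 and 257.7) in the order of the fast-fibre list (-0.20, 0.05 and 0.55 relative to all genes). Being itself 1 of the 17 genes of that list, Tnni2 shares this order partly by construction. How much muscle each sample held was not tested, so these levels need not be those of bone cells. Of 17 fast-fibre genes, 13 had lower means in the mutants, with a shift of -0.27 relative to the other genes that did not pass (camera adjusted p = 0.0665). Mybpc2 was 1 member past 0.05 when adjusted over the list alone (0.0226), against 0 over all probe sets, and Cacng1, a subunit of the muscle calcium channel, was at 0.49 ± 0.25. Slow-fibre genes were higher in 8 of 11 (shift 0.24, adjusted p = 0.264), with the slow myosin gene Myh7 at 0.71 ± 0.33 and Myl3 at 0.68 ± 0.32. Of 9 myogenic and perinatal genes 4 were higher and 5 lower (adjusted p = 0.599), among them Myl4 at -0.46 ± 0.27 and Des at 0.32 ± 0.35. The fast-fibre list passed with array weights (-0.52, adjusted p = 0.00024), without wild-type replicate 1 (-0.44, adjusted p = 0.00075) and without mutant replicate 3 (-0.41, adjusted p = 0.0219), and was at -0.06 without wild-type replicate 3. The slow-fibre list passed without wild-type replicate 3 (0.39, adjusted p = 0.0321), but was at 0.077 without wild-type replicate 1, 0.076 without mutant replicate 3 and 0.0086 with array weights. The myogenic list, at -0.09 with all arrays, was at 0.061 without wild-type replicate 3 and 0.011 without mutant replicate 1, and Des was at -0.11 without wild-type replicate 1. The fast- and slow-fibre lists had an adjusted p of 0.95 with an estimated correlation over all arrays.

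Regulators of the hypoxia-inducible factors were mostly higher, with 8 of 9 above the wild-type mean and a shift of 0.43 that narrowly missed the threshold (camera adjusted p = 0.0514). Hif3a and Egln3, a prolyl hydroxylase that marks these factors for degradation, were the 2 members past 0.05 when adjusted over the list alone (smallest value 0.00125), against 0 over all probe sets. Egln3 was at 16.5 ± 7.67 in the wild-type and 41.4 ± 13.4 in the mutants (SD, n = 3; 1.41 ± 0.40). Among 17 hypoxia targets and glycolytic genes, 11 were higher and 6 lower (shift 0.23, adjusted p = 0.302). Ddit4 was the 1 member past 0.05 adjusted over the list alone (0.0013), and the mitophagy gene Bnip3 was at 1.36 ± 0.47 on its brighter probe set and 0.71 ± 0.23 on the other. The 6 genes of the VEGF family and receptors showed a shift of 0.03 (adjusted p = 0.970), with Nrp2 at 0.35 ± 0.33 and Nrp1 at 0.32 ± 0.34. Of 14 endothelial genes 9 were higher, with a plain mean of 0.08 and a shift of -0.02 relative to the other genes (adjusted p = 0.968), including Ramp2 (0.54 ± 0.20) and Ptprb (0.43 ± 0.23). The list of HIF regulators passed with an intensity trend (adjusted p = 0.047) and without wild-type replicate 2 (adjusted p = 0.0459), wild-type replicate 3 (adjusted p = 0.0326) or mutant replicate 2 (adjusted p = 0.0112). It was at 0.19 (camera adjusted p = 0.426) without the dimmest 25% of probe sets, among which is Hif3a. Hypoxia targets passed without wild-type replicate 2 (0.40, adjusted p = 0.0246), but were at 0.087 without wild-type replicate 1 (adjusted p = 0.708) and 0.14 with array weights. For the HIF regulators and hypoxia targets an estimated correlation over all arrays gave an adjusted p of 0.95. Without wild-type replicate 1 the VEGF list was at -0.056, Nrp1 at -0.10 and Nrp2 at -0.015.

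Osteoclast genes were higher in 8 of 10, with a shift of 0.26 (camera adjusted p = 0.0665), and 3 members passed when adjusted over the list alone against 0 over all probe sets. These were the resorption enzymes Ctsk (199.9 ± 71.7 and 439.7 ± 140.3; 1.16 ± 0.34), Acp5 (0.72 ± 0.23) and Mmp9 (0.78 ± 0.25), at 0.0378 each. Matrix proteases and inhibitors were higher in 10 of 11 (shift 0.27, adjusted p = 0.174), led by Mmp13, the collagenase of hypertrophic cartilage, at 233 ± 85.2 and 493.8 ± 172 (1.10 ± 0.34). All 4 osteoclast regulators were higher (adjusted p = 0.481), with Lgr4 at 0.66 ± 0.31 and Tnfsf11, which encodes RANKL, at 0.22 ± 0.23. The osteoclast list passed without the dimmer part of the probe sets (0.47, adjusted p = 0.0161) and without wild-type replicate 3 (0.32, adjusted p = 0.0321). Its adjusted p was 0.257 without wild-type replicate 2, 0.131 with array weights and 0.95 with an estimated correlation. The shift of the matrix proteases and inhibitors was 0.13 without wild-type replicate 1 (adjusted p = 0.51) and 0.18 without mutant replicate 1 (adjusted p = 0.348).

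Bone and cartilage markers showed no shift that passed. The 12 osteoblast and bone matrix genes were divided into 6 higher and 6 lower (shift -0.13, camera adjusted p = 0.503), with Smpd3 at -0.65 ± 0.31 and the transcription factor gene Dlx5 at 0.36 ± 0.20. Of 4 osteocyte genes 2 were higher (adjusted p = 0.754), with the matrix phosphoprotein gene Dmp1 at 0.73 ± 0.33 and Phex at 0.54 ± 0.41. Resting and proliferating chondrocyte genes were higher in 15 of 19, by a shift of 0.08 (adjusted p = 0.470), with Chad at 0.55 ± 0.26 and Fgfr3 at 0.40 ± 0.21. The hypertrophic chondrocyte list, with 7 of 11 higher, was at 0.08 (adjusted p = 0.754), and Slc38a3 in it was at 0.58 ± 0.19. Joint cartilage genes were higher in 5 of 6 (shift 0.28, adjusted p = 0.174), with the lubricin gene Prg4 at 0.92 ± 0.39 and Cilp at 0.55 ± 0.21. Tendon and periosteum genes were at 0.01 (8 of 12 higher, adjusted p = 0.823), with Mkx at 0.51 ± 0.22 and Postn at 0.36 ± 0.21. The osteoblast shift was -0.03 without mutant replicate 2 and -0.32 without mutant replicate 3 (adjusted p = 0.0557), and on the same arrays left out Phex was at 0.94 and 0.08 and the osteocyte list at 0.37 and -0.0085. The tendon list was at -0.08 without wild-type replicate 3 and -0.12 without mutant replicate 3.

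No list of growth and patterning pathways passed, and the members named in each were chosen for their smallest p. In the growth hormone and IGF list 8 of 12 genes were higher (shift 0.16, camera adjusted p = 0.470), with the receptor genes Igf1r at 52.4 ± 19.8 and 107 ± 37.2 (1.05 ± 0.34) and Ghr at 18.5 ± 4.24 and 33.2 ± 6.72 (0.85 ± 0.24). The BMP and TGF-beta list was at 0.05 (8 of 13 higher, adjusted p = 0.791), but Id2, an inhibitor of DNA-binding factors that BMPs induce, was the 1 member past 0.05 when adjusted over the list alone (0.0231; 1.08 ± 0.25, from 36.9 ± 6.22 to 79.8 ± 24.6), and Tgfb3 was at 0.62 ± 0.23. Hedgehog and PTHrP genes were higher in 5 of 7 (adjusted p = 0.695), with the receptor gene Ptch1 at 0.69 ± 0.33 and Gli1 at 0.39 ± 0.19. Wnt targets and modulators were higher in 6 of 10 (adjusted p = 0.866), with the co-receptor genes Lrp6 at 0.71 ± 0.29 and Lrp5 at 0.38 ± 0.21. The Wnt shift of 0.01 lay between -0.029 without mutant replicate 3 and 0.088 without mutant replicate 2.

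Blood and fat cell markers did not pass either. Erythroid genes were higher in 3 of 4 (shift 0.22, camera adjusted p = 0.454), with Tfrc at 0.61 ± 0.24 and the heme synthesis gene Alas2 at 0.73 ± 0.31. Granulocyte genes were higher in 6 of 7 (0.10, adjusted p = 0.754), with Lcn2 at 0.79 ± 0.37 and S100a8 at 0.45 ± 0.32, and macrophage genes in 5 of 7 (0.11, adjusted p = 0.470), with Mrc1 at 0.54 ± 0.25 and C1qb at 0.45 ± 0.24. White adipocyte genes had a plain mean of 0.00 and a shift of -0.09 (3 of 5 higher, adjusted p = 0.754), with Car3 at -0.43 ± 0.33 and Fabp4 at 0.23 ± 0.25. Single arrays turned 3 of these shifts: without wild-type replicate 2 the granulocyte list was at -0.28 (adjusted p = 0.132) and the erythroid list at -0.064, without mutant replicate 1 the erythroid list was at -0.10 (adjusted p = 0.997), and without wild-type replicate 3 the white adipocyte list was at 0.015. The single measured genes of platelets, brown fat and nerve were Pf4 (0.24 ± 0.22), Cox8b (0.22 ± 0.27) and Pmp22 (-0.02 ± 0.21).

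Housekeeping and stress lists completed the set. Oxidative phosphorylation genes were higher in 15 of 27, with a plain mean of 0.01 and a shift of -0.08 (camera adjusted p = 0.503), among them Sdha (0.28 ± 0.23) and Cycs (-0.42 ± 0.38, and -0.24 ± 0.33 on its other probe set). Immediate early and heat shock genes were lower in 8 of 11 (shift -0.31, adjusted p = 0.130), with Egr3 at -0.30 ± 0.20 and Fosb at 129 ± 178 and 32.2 ± 12.3 (-0.99 ± 0.85). Circadian clock genes were higher in 5 of 6 (shift 0.26, adjusted p = 0.511), with Per1 at 1.19 ± 0.50 and Tef at 0.30 ± 0.21. The oxidative phosphorylation list passed with array weights (-0.23, adjusted p = 0.0248) but lay between -0.24 and 0.061 with each array left out in turn, where it did not pass. The immediate early list passed without wild-type replicate 3 (-0.50, adjusted p = 0.0262), but was at 0.0026 without wild-type replicate 2 (adjusted p = 0.992), the array on which Fosb was at 334. The circadian shift was 0.016 without mutant replicate 1. For the oxidative phosphorylation and immediate early lists as well the adjusted p was 0.95 with an estimated correlation. In the lists for which no such count is given, 0 members passed when adjusted over the list alone.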

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

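The alternatives reported here were planned, and none was added after the results were seen. The fall of the cell division list was kept in every fit with the preset correlation, with each array left out in turn giving shifts of -0.66 to -0.40 and adjusted p-values of 6.1e-09 to 0.00038. Quantile normalization and median centring changed no call, though the tendon list's shift crossed to -0.0013 after the former. The count of probe sets called higher was 4 with array weights, and at an unadjusted p under 0.05 with at least 1.5-fold it was 398 higher and 95 lower; with each array left out it was 0 to 15 higher and 0 lower. Probe sets at an unadjusted p under 0.05 numbered 323 without the dimmer part of the probe sets, where fewer were tested, 1412 with array weights, and 322 to 974 with each array left out. Lists called higher numbered 1 without the dimmer part of the probe sets, 1 with an intensity trend and 0 to 3 with each array left out. Lists called lower numbered 1 without the dimmer part of the probe sets, 0 with an estimated correlation, 0 with fry and 2 to 4 with each array left out. Array weights, from 0.232 for wild-type replicate 1 to 2.151 for wild-type replicate 3, took Hif3a to 1.98, while Vegfa (-0.065), Des (-0.12), Nrp2 (-0.081), Cox8b (-0.013), the VEGF list (-0.086) and the epidermal list (-0.028, with camera's direction upward) turned, and the Wnt (-0.027) and hypertrophic chondrocyte (-0.0016) lists crossed 0 in their shift but not in camera's direction; the cause was not tested. Without the dimmer part of the probe sets the endothelial list turned to 0.11, and the macrophage (-0.0097) and tendon (-0.022) lists crossed 0 in their shift only. With fry, whose value is the plain mean, the endothelial (0.078), white adipocyte (0.004) and oxidative phosphorylation (0.011) lists were above 0, as were the myogenic genes (0.0042), for which fry's direction stayed downward. With each array left out in turn, Hif3a was at 1.52 to 1.98 and Vegfa at 0.02 to 0.37, and the following crossed 0: Tnni2 (-0.46 to 0.21), Des (-0.11 to 0.70), Nrp2 (-0.015 to 0.57), Nrp1 (-0.10 to 0.62), Pmp22 (-0.17 to 0.093), Fosb (-1.68 to 0.24), Fabp4 (-0.0047 to 0.36), Cox8b (-0.022 to 0.41), and the lists for VEGF (-0.056 to 0.12), granulocytes (-0.28 to 0.31), myogenic genes (-0.23 to 0.061), white adipocytes (-0.17 to 0.015), tendon (-0.12 to 0.13), Wnt (-0.029 to 0.088), oxidative phosphorylation (-0.24 to 0.061), erythroid cells (-0.10 to 0.51), endothelium (-0.057 to 0.0096) and osteocytes (-0.0085 to 0.37), while the circadian list (0.016 to 0.53) turned in camera's direction but not in its shift, and the immediate early list (-0.50 to 0.0026) in its shift but not in camera's direction. Leaving out the dimmest 25% of the probe sets removed Hif3a, so it has no value there. The deviations of same-numbered wild-type and mutant arrays from their group means were correlated at r = -0.107, -0.026 and 0.315, against -0.421 to 0.338 for the other pairs. The levels of wild-type and mutant replicate 3 were correlated at 0.974, the highest of any 2 arrays. With 3 arrays per group these values cannot tell whether the numbers mark pairs, and the labels do not say that a number marks a litter. With the replicate block limma called 0 probe sets, 681 had an unadjusted p under 0.05, 4 lists were called lower, fast-fibre genes among them (adjusted p = 0.0323), and 1 higher, the HIF regulators (adjusted p = 0.0467). Detection p-values were not used here, so what signal over background limits could not be measured beyond the 52 probe sets under 20 on all wild-type arrays.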

Other observations

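The lists for FoxO, glucocorticoid, p53, cytoskeletal and lipid synthesis genes were written after the top genes had been seen, and the tests of skin, of marrow and of array brightness on the cell division list and on the share of higher probe sets were chosen only after those results were seen. Of the targets of the FoxO transcription factors, which insulin signalling holds in check, all 15 members not seen before had higher means in mutant bone, 8 of them at an unadjusted p under 0.05 and 0 past an adjusted p of 0.05 in limma. As a group they did not pass with an estimated correlation (camera p = 0.086, or 0.43 adjusted over the lists written after the top genes). With fry, which makes no comparison with other genes, p was 0.039 with no adjustment over those lists. The FoxO targets not seen before include Foxo3 (1.07 ± 0.34), Foxo1 (0.87 ± 0.27), Pink1 (0.84 ± 0.26), Txnip (0.72 ± 0.21) and the autophagy gene Map1lc3b (0.71 ± 0.24). Of 11 glucocorticoid-induced genes not seen before, 10 had higher means, among them Klf15 (1.40 ± 0.40), Klf9 (1.17 ± 0.43) and Nfkbia (1.09 ± 0.34), with Rhob as the exception (-0.13 ± 0.35). Relative to all genes, these FoxO targets stood at 0.56, 0.49 and -0.10 on the mutant arrays, all above the wild-type arrays at -0.41, -0.29 and -0.24. The glucocorticoid-induced genes stood at 0.58, 0.51 and -0.19 on the mutant arrays and -0.50, 0.026 and -0.42 on the wild-type arrays, so that mutant replicate 3 lay below wild-type replicate 2.

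Genes of the actin and tubulin cytoskeleton were lower in 18 of 23 members not seen before, with Tagln2 at -0.64 ± 0.24, Acta2 at -0.62 ± 0.24 and Capg as an exception at 0.56 ± 0.20. Their shift from the other genes was -0.27 (limma camera p = 0.00036, and limma camera p = 0.313 with an estimated correlation). Their plain mean of -0.18 had a limma fry p of 0.468, with no adjustment over those lists. Whether the group moved beyond its shared variation stays open. Sterol and fatty acid synthesis genes were lower in 9 of 15, led by Sqle (-0.66 ± 0.24).

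The genes of smallest p were mostly higher in the mutants, and FoxO-driven or glucocorticoid-induced expression is a candidate explanation for them. Unseen FoxO targets were shifted by 0.63 (camera p = 1.7e-08; 0.51 to 0.84 with each array left out) and unseen glucocorticoid-induced genes by 0.60 (camera p = 0.0006), but with an estimated correlation the p-values were 0.086 and 0.172, and with fry 0.039 and 0.134, so both stay open, and Klf15 and Pdk4 are in both lists. Hif3a, Ddit4, Per1 and Lcn2, named above in the HIF regulator, hypoxia, circadian and granulocyte lists, are also in the glucocorticoid list. Bnip3, of the hypoxia list, is also in the FoxO list. The levels of these genes thus do not tell such readings apart. For p53 targets the shift was 0.13 (camera p = 0.531) and for lipid synthesis genes, which fasting would lower, it was -0.21 (camera p = 0.0092, and p = 0.442 with an estimated correlation and 0.640 with fry), and neither test decided. The low brightness of wild-type replicate 1 was not decided: the median log2 difference of the 12 top genes was 1.67 with all arrays and 1.78 without it, but these were chosen for their difference, and the share of higher probe sets at an unadjusted p under 0.05 was 48.4% without that array but 66.0% after median centring, which removes differences in brightness. Of the 10 splits of the 6 arrays, 2 gave at least 669 probe sets at an unadjusted p under 0.05, and the real split with 669 was 1 of these. The other had 1107, for wild-type replicate 1 with mutant replicates 1 and 2 against the rest. At an adjusted p under 0.05 in limma, the real split gave 0 probe sets. The split of wild-type replicates 1 and 2 with mutant replicate 2 against the rest gave 8, and every other split gave 0. The epidermal list was high on those 3 arrays, but whether skin gave these calls was not tested. With 10 splits there are too few for a share under 0.05.

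The lower level of epidermal genes in the mutants may come from skin carried over with the bone in some samples, unrelated to genotype. The list mean ranged over 4.715 on the log2 scale, or 26.3-fold, among the wild-type arrays alone, against a difference between the group means of -1.82, and every pair of its genes was correlated across the 6 arrays at 0.947 or more. A difference in skin between the genotypes was not tested and stays open.

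For the lower cell division genes, the tables argue against the low overall brightness of wild-type replicate 1 as the whole cause: a dim wild-type array would raise the plain mean log2 difference, which was -0.40. Quantile normalization moved the probe sets at an unadjusted p under 0.05 from 669 to 854 and left the list's shift at -0.49 with the preset correlation (adjusted p = 6.4e-06). A shift from the other genes cancels a brightness shared by all genes of an array, so this unchanged shift does not bear on that cause. The lower level could reflect fewer dividing cells in mutant bone, which was not tested directly. A smaller share of marrow cells stays open: the median log2 difference of 11 erythroid and granulocyte genes was 0.091 against -0.35 for the cell division genes, but without wild-type replicate 2 it turned to -0.15 against -0.48, a gap of 0.33 within the SD of the marrow genes (0.46). All 10 splits of the 6 arrays gave at least the 3 lists of the real one, the highest other giving 12 with camera's preset correlation. The number of lists called with the preset correlation thus did not set the genotypes apart from other groupings of these arrays. Which lists the other splits called was not examined, and 10 splits are too few for a share under 0.05.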
